A study of Mus musculus with 4 samples.

How the data were processed

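Total RNA from whole brain of SAMP8 mice on a control diet (LSO), SAMP8 mice on a diet with whale meat extract (WME) and SAMR1 mice on the LSO diet was labelled with Cy3 and Cy5 and hybridised to 4 Agilent mouse arrays, per the labels' protocols. Arrays 1 and 2 carried SAMP8 WME against SAMP8 LSO with the dyes exchanged, and arrays 3 and 4 carried SAMP8 LSO against SAMR1 LSO in the same way. All 4 arrays lay on 1 slide, so no slide or scan batch could be compared. The arrays of a pair were taken as 1 replicate because the labels describe them as a dye swap of the same RNAs.

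The deposited scanner files hold spot intensities, made with Agilent Feature Extraction 11.0.1.1 per the file headers and the submitters' processing notes. Per the file headers, the median intensity and local background of each spot are raw, and the processed intensities are background-subtracted and dye-normalized by the same program. The log10 ratio of red over green in those files was made from the processed signals, per the file headers, and was not used beyond checking that. The deposited series table holds log2 ratios. Each of its columns equalled log2 of red over green processed signal of its array on all features (largest difference 5e-09), so its values were neither turned for the dye swap nor centred again. Its column medians were −0.018, 0.012, 0.0036 and 0.017. Flags for spots above background, saturated spots and outliers were used as the deposited files give them. How many mice stood behind an RNA is not given in the sources used here.

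From these files, median spot intensities were background-corrected with normexp and an offset of 50 and normalized within each array by loess in limma 3.58.1 (R 4.3.3), with control spots at weight 0. The design written before the data were examined named mean signals, and median signals were used because the files examined held no mean signal. The offset pulls the ratios of dim probes towards 0. Spots marked as outliers by Feature Extraction (105 to 123 per array) were left out, and the spots of a probe were averaged. Spike-in controls had an observed to expected log ratio slope between 0.896 and 0.902, as Feature Extraction computed it. Ratios of the swapped arrays were turned so that each was WME over LSO or SAMP8 over SAMR1, and both arrays were averaged.

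Probes were named through RefSeq accessions in the gene table of assembly GRCm38.p6, used for names and gene order only because the array files name another build. Of 41174 probes, 23374 were named through an accession, 10 by a symbol in the file and 17790 had no match and kept the file's accession. A gene was represented by its probe with the highest mean log2 intensity, and 5455 of 16543 named genes had more than 1 probe. A gene counted as measured when its probe was well above background in at least 1 RNA of the pair on both arrays. With 1 RNA per group no test across genes was run. A gene was called when its ratio was at least 1.5-fold in the same direction on both arrays. Where the dimmer RNA was not well above background on either array, the fold is a lower bound, taken against the higher of the lowest signal among probes well above background and the probe's own.

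Named genes were the 15 with the highest and the 15 with the lowest mean log2 ratio among called genes with a gene name, passing over clone and predicted-locus names, and 1 of them is not reported here. Up to 4 called members of each gene list were also named, or up to 2 members with the largest ratio where none was called, and up to 10 genes per direction for the overlap of the comparisons. The members of the immediate early and kidney lists named beyond this rule, Hspb1 in the indirect ratio and the other probes printed were chosen after their values were seen. The 50 gene lists were fixed before the data were examined, and 3 more (kidney, liver and nasal mucosa transcripts) were written after the values were seen. A list was described by the percentile of its median among 10000 random lists drawn from 20 bins of expression and was called outside beyond the central 95% of them. This describes these RNAs and is not a test of the conditions, and genes of a list do not vary independently.

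The overlap of the comparisons was set against the product of the numbers of calls and against 200 simulations that put each gene's diet difference on the shared RNA or on the WME RNA with equal chance and added the strain difference of another gene of similar expression. Technical error was estimated from the difference between the dye terms of both pairs, which cancels RNA differences and probe dye bias. The steps were tested on simulated scanner files that had the real levels, dye bias and noise, with 200 genes changed per comparison. Of 50 genes changed 4-fold, 50 were called in the right direction in each comparison. Of 50 changed 2-fold, 39 of the diet and 37 of the strain simulation were called, and of 50 changed 1.5-fold, 1 and 0 were called. The median estimated log2 ratios of the genes changed 1.5-fold were 0.52 and 0.48. These lay below the limit of 0.585, which both arrays must pass. No gene left unchanged was called among 26464 and 26739. The list percentile was tried on the real arrays, not on simulated ones. Without a planted shift, 5 of 40 random lists of 15 genes in the diet comparison and 1 of 40 in the strain comparison lay outside the central 95%. With a shift of 0.1 on the log2 scale 40 and 37 of 40 did.

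The alternatives tried were Feature Extraction's processed signals, the deposited series table, no background correction, median centring in place of loess, Aquantile scaling between arrays, other rules for dim probes, other limits of size, each array alone, outlier spots kept and the median over a gene's probes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the counts, lists and simulations.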

Results

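Messenger RNA levels in whole brain were compared between mice of 2 inbred strains with 4 two-colour microarrays. SAMP8 is a senescence-accelerated strain that develops learning and memory deficits early, and SAMR1 is the senescence-resistant strain commonly used as its control. SAMP8 mice received either a control diet with safflower oil (LSO) or a diet supplemented with whale meat extract (WME), and SAMR1 mice received the LSO diet only. The diets began at 24 weeks of age and lasted 26 weeks, behaviour was tested over 8 days at 49 weeks, and brains were taken at 50 weeks. Each array carried a pair of RNAs, and each pair was hybridised on 2 arrays with the dyes exchanged. The labels give no number of mice behind an RNA and do not say whether RNAs were pooled. The design therefore holds 1 RNA per group and 1 replicate per comparison, the differences have no replicate check, and no p-values are given. The error given with each log2 ratio is the SD over the 2 dye orientations, which measures technical error only. It includes the probe dye bias that the mean of both arrays cancels, so it is not the error of that mean. An SD of 2 values is itself imprecise.

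On each array 43379 probe spots for 41174 distinct probes were read. Between 81.4% and 85.6% of the probe spots were well above background in a channel, and 0 were saturated. Median spot signals were 275 to 321 in Cy3 and 306 to 357 in Cy5, against median backgrounds of 65 to 71.5 and 72.5 to 75.5. The small number of arrays limits the precision of every value. A gene was called higher or lower when it differed by at least 1.5-fold in the same direction on both arrays of its pair.

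The diet comparison asked how the WME diet changed gene expression in SAMP8 brain. Kap, which encodes the kidney androgen-regulated protein, stood 21.7-fold higher in the WME RNA than in the LSO RNA (log2 ratio 4.44 ± 0.92, SD, 2 arrays of 1 RNA pair). Pomc, the precursor of corticotropin, melanocortins and beta-endorphin, was 3.39-fold higher (log2 ratio 1.76 ± 0.15). The lower genes included S100a9 and S100a8, calcium-binding proteins of neutrophils (log2 ratios −1.09 ± 0.06 and −0.80 ± 0.12). Fos and Egr2, transcription factors switched on quickly by neuronal activity, were also lower, at log2 ratios of −0.91 ± 0.19 and −0.65 ± 0.04. In all, 15 of 26664 measured genes and unnamed transcripts were higher and 8 were lower, of which 10 and 6 had a gene name.

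The other named genes that were higher with WME were mostly metabolic enzymes and transporters that are abundant in kidney. Dnase1, a secreted endonuclease, was 3.99-fold higher (SD of its log2 ratio 0.80), and the cytochrome P450 gene Cyp4b1 was 3.28-fold higher (1.71 ± 0.53). Acsm2, an acyl-CoA synthetase for medium-chain fatty acids, had a log2 ratio of 1.52 ± 0.74. Fbp1, an enzyme of gluconeogenesis, had one of 1.35 ± 0.45. Slc34a1, the sodium-phosphate cotransporter of the renal tubule, and Klk1, tissue kallikrein, had log2 ratios of 1.21 ± 0.59 and 1.16 ± 0.62. Cyp2e1 was at least 2.01-fold higher, because its probe was not well above background in the LSO RNA, and it was not called under median centring. Feature Extraction's processed signals gave larger log2 ratios for these genes, 5.94 for Kap and 4.40 for Dnase1. Of the 15 genes, 8 were among 39 transcripts abundant in kidney, a list written after the values were seen, and 7 were higher without that list. The cytochrome P450 genes expressed in the olfactory mucosa, Cyp2g1 (−1.03 ± 0.37) and Cyp2a5 (−0.72 ± 0.10), completed the named genes that were lower. Cyp2a5 has near-identical copies in the genome, so its value is uncertain.

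**Figure D1:**
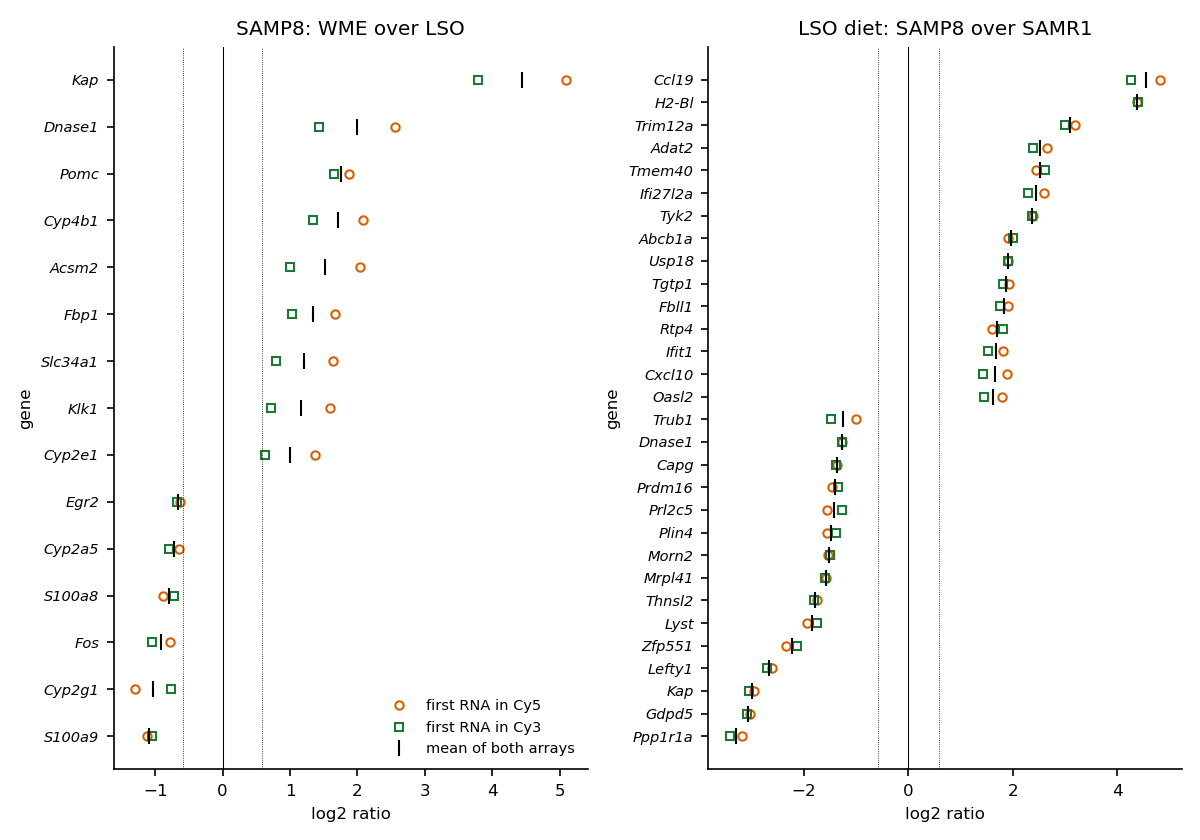
Log2 ratios of named genes past the size rule in the diet comparison (left) and the strain comparison (right), with an open symbol for each dye orientation and a bar for the mean of both arrays; dotted lines mark 1.5-fold. Kap had the highest mean in the diet comparison, at 4.44, and one of the lowest in the strain comparison, 8.01-fold lower.

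Most transcripts differed little between the diets. The SD of the diet log2 ratios over genes was 0.083, against 0.201 in the strain comparison, and 88.0% of genes lay within 0.1 of 0. After the sign was turned for dye, the ratios of both arrays of the diet pair correlated at r = −0.27 across genes, which are not independent replicates. The part of the log2 ratio that followed the dye had an SD of 0.109, larger than the part that followed the RNA. A further 40 genes passed 1.5-fold on both arrays with opposite signs, as no RNA difference gives. A contrast of the arrays that cancels both the RNA difference and each probe's dye bias had an SD of 0.049, and 0 genes passed 1.5-fold in it.

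**Figure D2:**
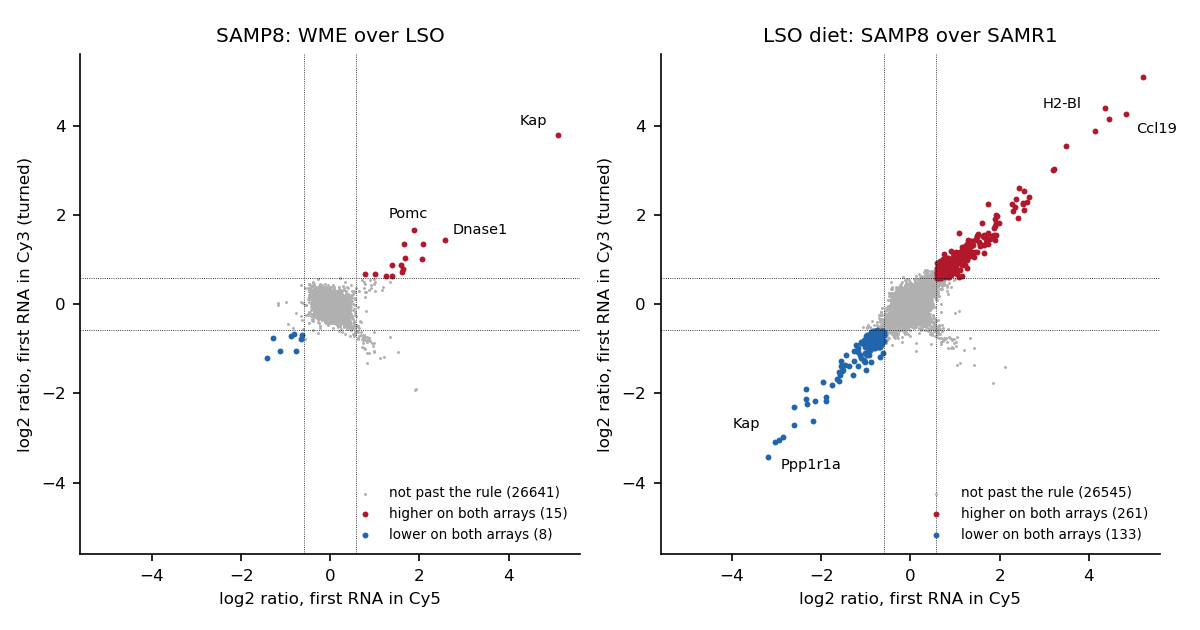
Log2 ratio of each gene with the first-named RNA in Cy5 (x axis) and, with the sign turned, in Cy3 (y axis), for the diet pair (left) and the strain pair (right). Coloured points passed 1.5-fold in one direction on both arrays, 15 higher and 8 lower with WME and 261 higher and 133 lower in SAMP8; grey points beyond the dotted lines at lower right changed sign with the dye.

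Gene lists fixed before the data were examined were described by their median log2 ratio and its percentile among 10000 random lists of the same size and expression. The immediate early genes, which neuronal activity induces within minutes, had the lowest median in the diet comparison, −0.35 (percentile 0). Of 18 members, 13 were below 0 on both arrays, and Fos and Egr2 passed 1.5-fold, Egr2 not under median centring. Nr4a1 (−0.67 ± 0.16), Npas4 (−0.69 ± 0.36), Junb (−0.49 ± 0.14), Ier2 (−0.49 ± 0.20, its other probe at 0.13) and Dusp1 (−0.47 ± 0.26) passed it on 1 array each. Blood cell markers had a median of −0.24 (percentile 0), with 8 of 10 below 0 on both arrays and S100a8 and S100a9 past the rule. Cerebellar markers had a median of −0.23 (percentile 0). Among them 11 of 12 were below 0 on both arrays and 0 passed 1.5-fold, with Cbln1, a synaptic organiser of granule cells, at −0.29 ± 0.08 and En2 at −0.27 ± 0.13.

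The medians of the major histocompatibility genes (−0.12) and the interferon stimulated genes (−0.10) were also below the random range, with 0 members called. Heat shock and chaperone genes had the highest median, 0.18 (percentile 100). Of 15 members, 10 were above 0 on both arrays, led by Hspa1a (0.47 ± 0.24) and Hspa1b (0.41 ± 0.12), inducible chaperones of the HSP70 family that are near-identical to each other. Glutamatergic neuron markers had a median of 0.09 (percentile 100), GABAergic markers 0.049 (99.8) and glucocorticoid responsive genes 0.070 (99.9), each with 0 called. Pituitary markers had a median of 0.060 (98.7), and Pomc was the member past the rule. Astrocyte (−0.10), endothelial and mural (−0.094) and meningeal (−0.14) markers also lay outside the random range, but each turned positive when arrays were centred on the median without the intensity-dependent loess. In that setting the median of all measured genes was itself 0.066. The endothelial and mural (0.055) and meningeal (0.043) medians stayed below it, and the astrocyte median (0.12) lay above it. Of the 50 lists, 11 lay above the random lists, 11 below and 28 inside. Of 40 lists of 15 genes drawn at random from these same arrays, 5 lay outside in the diet comparison. Such lists do not show how often lists of genes that vary together lie outside. The genes for cholesterol synthesis had a median of −0.033 (2.07), also positive under median centring. Those for fatty acid synthesis (−0.0093), fatty acid oxidation (0.033), carnitine and carnosine (0.0036), antioxidants (−0.021) and synaptic plasticity (0.0041) lay inside the random range.

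The strain comparison set SAMP8 against SAMR1 brain, both on the LSO diet. Interferon-induced and antigen presentation genes were among those higher in SAMP8. Ccl19, a chemokine that attracts T cells and dendritic cells, was 23.3-fold higher (log2 ratio 4.54 ± 0.40), and H2-Bl, a class I histocompatibility gene, was 20.9-fold higher (4.39 ± 0.02). Among genes lower in SAMP8, Ppp1r1a, an inhibitor of a serine/threonine protein phosphatase, was 9.87-fold lower (−3.30 ± 0.17), and Gdpd5, a glycerophosphodiester phosphodiesterase, was 8.36-fold lower (−3.06 ± 0.03). In all 261 of 26939 measured genes were higher in SAMP8 and 133 were lower, of which 155 and 63 had a gene name. The turned ratios of both arrays correlated at r = 0.57 across genes, and 40 genes passed 1.5-fold with opposite signs.

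Other genes with the highest ratios in SAMP8 had varied functions. Trim12a had a log2 ratio of 3.10 ± 0.13 and Adat2, a subunit of a transfer RNA deaminase, one of 2.53 ± 0.19. Tmem40 stood at 2.52 ± 0.12. Tyk2, a kinase of interferon and interleukin receptors, was 5.18-fold higher (2.37 ± 0.01), and Abcb1a, the P-glycoprotein drug pump of brain endothelium, was 3.89-fold higher (1.96 ± 0.06). Fbll1, a fibrillarin-like gene, was 3.56-fold higher (1.83 ± 0.10). Below Gdpd5, the lowest ratios were those of Kap (8.01-fold lower, SD of its log2 ratio 0.07) and Lefty1, an inhibitor of nodal signalling (−2.66 ± 0.07). The zinc finger gene Zfp551 (−2.24 ± 0.16) and the lysosomal trafficking gene Lyst (−1.85 ± 0.14) came next. Thnsl2, Mrpl41 of the mitochondrial ribosome, Morn2, the lipid droplet gene Plin4, Prl2c5, Prdm16, a transcription factor of brown fat, Capg, which caps actin filaments, Dnase1 and Trub1 had log2 ratios from −1.78 to −1.24. Ccl19, H2-Bl, Trim12a, Tgtp1, Prl2c5 and Oas genes have near-identical copies, so their values are uncertain. Of 99 other probes for the called genes, 82 had the same sign and 43 also passed 1.5-fold, so that many calls rested on 1 probe. The other probes stood at 3.06 and 1.21 for H2-Bl, 1.09 for Trim12a, 0.95 for Tmem40 and −0.10 for Trub1. Feature Extraction's processed signals gave larger folds where 1 RNA of the pair was dim, 67.1 for H2-Bl, 45.1 for Trim12a, 18.9 for Tyk2 and 7.85 for Usp18, and 22.3-fold lower for Lefty1, so the sizes of folds in this comparison depend on the processing.

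Of 15 measured interferon stimulated genes, 10 were higher in SAMP8 and 0 lower, and all 15 had positive ratios (median 0.94, percentile 100). Usp18, a protease that removes ISG15 from proteins and damps interferon signalling, was 3.76-fold higher (1.91 ± 0.01). Ifit1, which binds viral RNA, was 3.18-fold higher (1.67 ± 0.21), Oasl2 was 3.08-fold higher (1.62 ± 0.24) and Oas1a 2.56-fold higher (1.35 ± 0.03). Processed signals gave 5.06-fold for Ifit1, 7.51-fold for Oas1a and 5.96-fold for Cxcl10. Outside this list Ifi27l2a (2.45 ± 0.22), Tgtp1 (1.87 ± 0.07) and Rtp4 (1.71 ± 0.15) were interferon-induced genes among the highest ratios, but the other probe for Tgtp1 stood at 0.14. Major histocompatibility genes had a median of 0.42 (percentile 100). Of 11 measured, 3 were higher, namely H2-T23 (0.75 ± 0.04), H2-Q7 (0.73 ± 0.05) and the immunoproteasome subunit Psmb9 (0.67 ± 0.02). Cytokines, chemokines and receptors had a median of 0.21 (percentile 100) and 2 of 17 were higher, Cxcl10, a T-cell chemokine (1.66 ± 0.33), and Cxcl13, a B-cell chemokine (1.11 ± 0.14). Complement genes had a median of 0.23 (percentile 100), yet the member past the rule, C4b, was lower (−0.83 ± 0.21).

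Vascular and connective tissue markers had higher medians in the SAMP8 RNA. All 13 endothelial and mural markers were above 0 on both arrays (median 0.38, percentile 100). Of these, 4 passed the rule, Abcb1a, the mural potassium channel gene Kcnj8 (0.96 ± 0.02), the pericyte receptor gene Pdgfrb (0.86 ± 0.21) and Rgs5 (0.83 ± 0.17). Meningeal and fibroblast markers had a median of 0.43 (percentile 100) with 4 of 12 higher, the collagen genes Col3a1 (0.96 ± 0.02), Col1a1 (0.86 ± 0.01) and Col1a2 (0.70 ± 0.06) and the proteoglycan gene Ogn (0.64 ± 0.05, not called under median centring). The other probes stood at −0.01 for Col3a1 and at 0.17 and 0.48 for Col1a1. Blood cell markers had a median of 0.42 (percentile 100), with S100a9 (1.31 ± 0.06) and S100a8 (1.11 ± 0.02) past the rule. Oligodendrocyte precursor markers (0.23) and microglia and macrophage markers (0.12) lay above the random range with 0 members called. Choroid plexus markers (−0.17) and ependymal markers (−0.19) lay below it, also with 0 called.

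Immediate early genes had a median of 0.39 (percentile 100) in SAMP8 and 5 of 18 were higher. These were Egr2 (1.15 ± 0.05), Fos (1.11 ± 0.17), Nr4a1 (1.00 ± 0.11), Arc (0.66 ± 0.04, not called under median centring) and Egr4 (0.64 ± 0.01). Glucocorticoid responsive genes had a median of −0.18 (percentile 0), with the kinase gene Sgk1 lower (−0.76 ± 0.05), and circadian clock genes one of −0.12 (percentile 0) with 0 called. Heat shock and chaperone genes had a median of 0.18 (percentile 100) with 0 called. Single members were past the rule in other lists. The choline transporter gene Slc5a7 (1.04 ± 0.12) and Spink8, a marker of hippocampal pyramidal cells (1.17 ± 0.15), were higher, and Timp3, an inhibitor of metalloproteinases (−0.63 ± 0.04), was lower. The nicotinic receptor gene Chrna4 was at 0.68 ± 0.07 on its brightest probe and at −1.76 on the other, so no direction is given for it. Of the 50 lists, 20 lay above the random lists, 10 below and 20 inside. The antioxidant (0.029), fatty acid synthesis (0.0021), synaptic plasticity (0.0087) and pan-neuronal (0.0014) lists were among those inside. Glutamatergic (−0.070, percentile 0.73) and GABAergic neuron markers (−0.074, percentile 0.22) lay below the random range, each with 0 called.

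**Figure D3:**
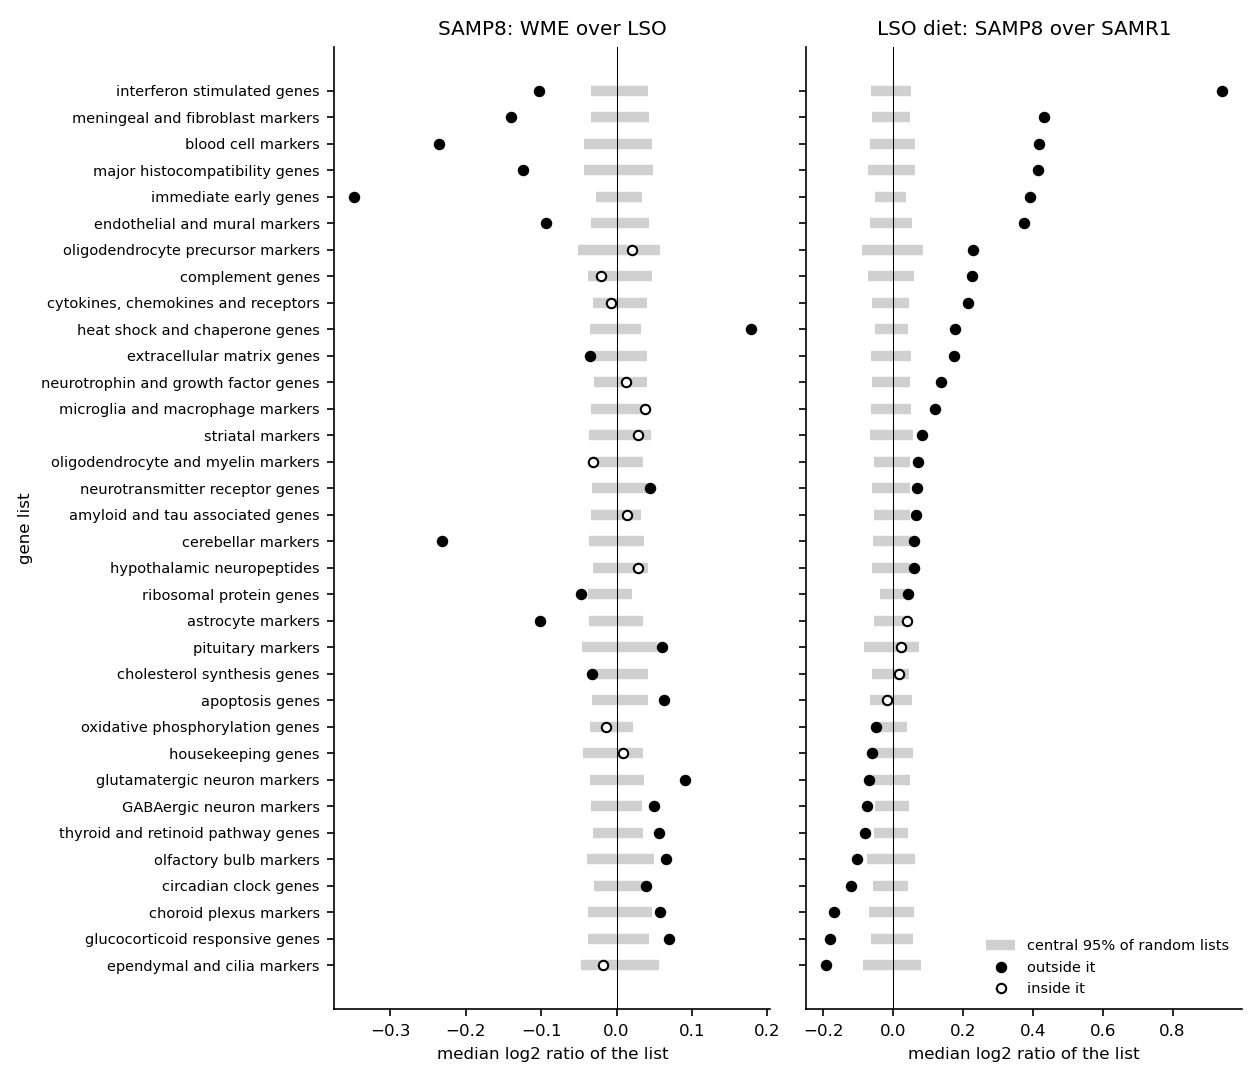
Median log2 ratio of each gene list that lay outside the central 95% of random lists in the diet comparison (left) or the strain comparison (right); the x axes differ in scale. Filled points lie outside the grey range of the random lists, and the interferon stimulated genes had the highest strain median, 0.94, with a diet median of −0.10.

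SAMP8 LSO RNA entered both comparisons, as the denominator for diet and the numerator for strain. It is taken here as the same RNA in both pairs, although the array titles give only strain, diet and dye. Of 26392 genes measured in both, 13 were called in both. All 13 went in opposite directions and 0 in the same direction. Those higher with WME and lower in SAMP8 than in SAMR1 included Kap, Dnase1, Cyp4b1 and Acsm2. The strain call of Acsm2 ended when both RNAs had to be well above background or probes were combined by their median, and its other probe stood at −0.33. Fos, Egr2, S100a8, S100a9, Cyp2g1 and Cyp2a5 were lower with WME and higher in SAMP8 than in SAMR1, with 2 transcripts without a usual gene name. If the lists were independent, 0.147 genes called in opposite directions and 0.185 in the same direction would be expected. In a simulation, each gene's diet difference was placed on the shared RNA or on the WME RNA with equal chance, and a strain difference of another gene of similar expression was added. It gave a mean of 9.88 opposite calls (central 95% of 200 simulations, 5 to 14) and 0.115 same calls. The log2 ratios correlated at r = −0.23 (Spearman's rho −0.22) across genes, against a simulated mean of −0.20 (−0.24 to −0.16). Their covariance was −0.00382 against a simulated −0.00345. The simulation carried the whole measured diet ratio, with the noise of its arrays, into the strain ratio. Technical SD was 0.049, against an SD of 0.083 of the diet ratios. At that equal chance, the simulated correlation and covariance are therefore larger in size than the shared RNA alone would give, by an amount that was not computed. The simulated opposite calls, correlation and covariance follow largely from the equal chance that was set. Their nearness to the observed values therefore does not show that the shared RNA accounts for the opposite movement. The simulation kept the wider spread of the strain ratios, and 3 exchangeable RNAs would give a correlation of −0.5. With 1 RNA per group the shared RNA could not be split, so part of the opposite movement may come from it. On arrays of a single dye orientation the correlation was positive, 0.14 and 0.21.

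**Figure D4:**
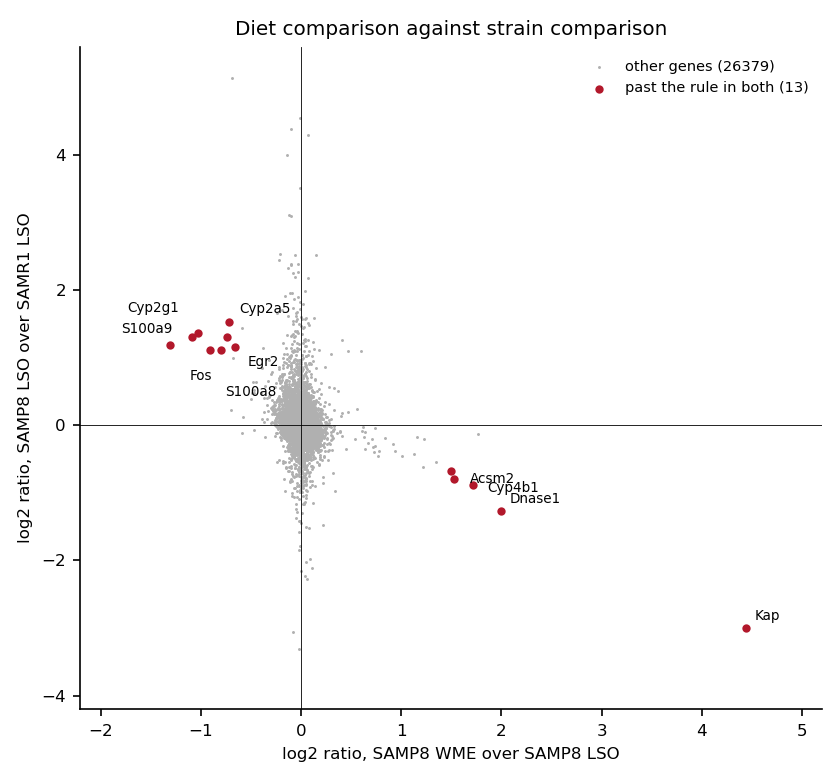
Log2 ratio of each gene in the diet comparison (x axis) against that in the strain comparison (y axis), each the mean of 2 arrays. Red points are the 13 genes called in both, all with opposite signs, and the others are grey.

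No array carried SAMP8 WME beside SAMR1 LSO, and this pair was described by the sum of the mean log2 ratios of both comparisons. Of the 381 genes called between the strains and measured in both comparisons, 348 still differed by at least 1.5-fold in this indirect ratio. The median gene kept 97.4% of its strain log2 ratio, and 248 of the 381 (65.1%) were smaller in the indirect ratio. This ratio reuses the strain ratio, so a gene without a diet difference keeps its value by construction, and error in the shared RNA also makes it smaller. Of the 23 genes called for diet, 14 lay closer to SAMR1 in SAMP8 WME than in SAMP8 LSO. Ccl19 stood 23.2-fold higher in SAMP8 WME than in SAMR1 LSO, Usp18 3.36-fold higher and Tyk2 4.83-fold higher, and Ppp1r1a had an indirect log2 ratio of −3.32. Pomc was 3.11-fold higher, and Kap, lower in SAMP8 LSO than in SAMR1, was 2.71-fold higher in SAMP8 WME than in SAMR1. The diet log2 ratios of Kap were 5.09 and 3.79 on the 2 arrays, so the size of its indirect fold is uncertain. Interferon stimulated genes had an indirect median of 0.77 (percentile 100) and immediate early genes one of 0.16 (percentile 100). Fos stood at 0.20 and Egr2 at 0.50. Heat shock and chaperone genes had an indirect median of 0.34 (percentile 100), with Hspb1 1.84-fold and Hspa1a 1.59-fold higher.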

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

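The kidney, nasal mucosa and blood list exclusions were chosen after the data were seen, and the other alternatives before. Feature Extraction's processed signals, and the deposited series table that equals them, called 63 genes higher and 40 lower for diet and 465 and 291 for strain. All 23 diet calls and 392 of the 394 strain calls were among these in the same direction. The diet calls they made had a median log2 intensity of 6.94, against 8.28 for the calls reported. The offset used for the reported calls pulls the ratios of dim probes towards 0 by construction, and whether it accounts for the added calls was not tested. With processed signals 34 genes were called in both comparisons in opposite directions and 2 in the same. Without background correction 31 genes were higher and 9 lower with WME, so that 77.5% of diet calls were higher, against 65.2%, and the cause was not tested. Requiring 2-fold on each array left 7 higher and 2 lower for diet, 101 and 38 for strain and 4 opposite calls in both, and 1.3-fold gave 27, 15, 488, 264 and 22, as the construction of those limits gives. A mean of 1.5-fold over both arrays gave 29 and 13 for diet and 1 gene in the same direction in both comparisons. A lower limit of 0.75 gave 13 lower for diet and 237 for strain. Without the kidney list 7 genes were higher with WME, and without the nasal mucosa and blood lists 4 were lower.

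A single array keeps the probe dye bias that the swap cancels. Each array alone called 15 to 81 genes higher and 20 to 62 lower for diet, 323 to 389 higher and 176 to 239 lower for strain, and 15 to 17 genes in opposite directions and 40 to 42 in the same direction in both comparisons. The correlation of diet and strain ratios turned positive (0.14 to 0.21), as did their covariance (0.00491 to 0.00564). The diet medians of choroid plexus markers (−0.0092 to 0.14), thyroid and retinoid pathway genes (−0.012 to 0.060) and ribosomal protein genes (−0.21 to 0.092) changed sign between the arrays. So did the strain medians of oxidative phosphorylation (−0.17 to 0.043), ribosomal protein (−0.047 to 0.17) and housekeeping genes (−0.14 to 0.084).

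Median centring in place of loess changed the sign of these diet medians: astrocyte (0.12), endothelial and mural (0.055) and meningeal (0.043) markers, and cholesterol synthesis (0.14), ribosomal protein (0.19) and extracellular matrix genes (0.063). It also changed the strain medians of oligodendrocyte and myelin markers (−0.028), amyloid and tau associated genes (−0.050) and ribosomal protein genes (−0.073). Under median centring the median of all measured genes itself moved, to 0.066 for diet and −0.026 for strain. The endothelial and mural, meningeal and extracellular matrix diet medians stayed below that of all genes. The strain median of oligodendrocyte and myelin markers lay near that of all genes. The other medians lay beyond it on the side of the new sign, and the cause of those changes was not tested. Of the lists outside the random range, 14 of 22 in the diet comparison and 25 of 30 in the strain comparison kept their sign under every alternative. These counts take the sign against 0, not against the median of all genes. Chrna4 turned to −0.54 with the median over its probes, whose ratios have opposite signs. Of the called genes that the naming rules picked, 9 of 18 in the diet comparison and 42 of 63 in the strain comparison passed 2-fold on each array. Under the changes of signal, background, normalization, filter and probe, 15 and 57 stayed called. Single arrays and looser size limits cannot lose a call by construction. Median centring ended the calls of Egr2 and Cyp2e1 for diet and of Arc and Ogn for strain, and the median over probes ended those of BC004786 for diet and Col1a1, Col3a1 and Acsm2 for strain. Requiring both RNAs well above background also ended that of Acsm2. Aquantile scaling cannot change a ratio within an array, and a slide block was not possible because all 4 arrays lay on 1 slide. No paired analysis was possible because each comparison holds 1 RNA pair.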

Other observations

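Some further gene lists had strain medians outside the random range with 0 members called. Among markers of regions, striatal markers had a strain median of 0.083 (percentile 99.6), with 9 of 11 above 0 on both arrays, and olfactory bulb markers one of −0.10 (percentile 0.37), led by Doc2g at −0.40 ± 0.22 and Cdhr1 at −0.35 ± 0.20. Hcrt, the precursor of the orexin peptides that promote wakefulness, stood at 0.50 ± 0.12 in SAMP8, and Avp, the vasopressin precursor, at −0.36 ± 0.03. The neuropeptide list as a whole had a strain median of 0.059 (percentile 98.8). Neurotrophin and growth factor genes had a strain median of 0.14 (percentile 100), with Vegfa, a growth factor for blood vessels, at 0.28 ± 0.05. The fatty acid transporter gene Mfsd2a, which carries omega-3 lipids across the blood-brain barrier, stood at −0.59 ± 0.14, uncalled. The strain median of its list lay inside the random range (0.0021, percentile 60.6). Slco1c1, a thyroid hormone transporter of the same barrier, stood at −0.52 ± 0.05. With WME, Cxcl13 stood at 0.60 ± 0.39, uncalled.

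The heat shock and chaperone list lay above the random range in both comparisons, and with the neurotransmitter receptor genes it was 1 of 2 lists with the same sign among 18 outside in both. The remaining 16 had opposite signs, the direction that the shared SAMP8 LSO RNA alone also gives.

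The tests below were chosen after the result they bear on was seen, except the tests of neighbouring genes and of other probes.

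Of 33 transcripts abundant in kidney, 8 were called higher with WME (list median 0.25), and of 30 measured in the strain comparison 4 were called lower in SAMP8 LSO than in SAMR1 and 8 had positive ratios. All 8 called for diet were below 0 in the strain comparison, 4 of them past the size rule, and above 0 (0.56 to 1.44) in the indirect ratio of WME to SAMR1. The 0.56 belongs to Cyp2e1, whose probe was not well above background in the SAMP8 LSO RNA of either pair, so its size is uncertain. All 8 had a larger diet log2 ratio on the array with WME in Cy5, with Kap at 5.09 and 3.79 and Slc34a1 at 1.63 and 0.80. Their strain arrays lay closer together, at −2.95 and −3.05 for Kap and −0.49 and −0.75 for Slc34a1. The cause of this difference between the diet arrays was not tested, so the sizes of these diet ratios are uncertain. The list holds 1 gene of a list fixed earlier, and 26 of its members were well above background in the SAMP8 LSO brain RNA. Kidney RNA in unequal traces in the brain RNAs stays open, because the list was written after the values were seen: the 25 members called in neither comparison had a diet median of 0.092 (percentile 100), with 18 above 0 on both arrays, while of its members Slc12a1 (0.0069 ± 0.08) and Aqp2 (−0.024 ± 0.16) lay near 0 and Umod (0.64 ± 0.39), abundant in the same segment as Slc12a1, and Cdh16 (0.71 ± 0.38) lay above 0. With processed signals these stood at 0.20 for Slc12a1, 0.0017 for Aqp2, 2.61 for Umod and 1.59 for Cdh16. RNA of other peripheral organs stays open too, since the liver list had a diet median of 0.029 inside the random range (percentile 91.6) with 7 of 14 above 0 on both arrays, and so does a diet effect on these genes in brain cells, which 1 RNA per group cannot separate from a difference between single brains or preparations.

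The median of the immediate early genes was below the random range with WME and above it in SAMP8 LSO over SAMR1, but only 2 of 18 were called lower for diet and 5 of 18 higher for strain. Whether the SAMP8 LSO RNA alone stood apart stays open. That cause predicted an indirect median of WME to SAMR1 inside the random range, and the median was 0.16 (percentile 100). The test cannot decide, because 16 of the 50 fixed lists lay above the random lists and 10 below in this ratio. Genes of a list also do not vary independently. A lower share of cerebellum in the WME RNA is argued against as the whole cause, since it lowers no gene by more than the region's own markers, yet 10 of 18 immediate early genes had a mean below the lowest cerebellar mean (−0.29) and 4 lay, on each array, below the lowest value of a cerebellar marker on an array (−0.43). As part of the cause it cannot be told apart with 1 RNA per group. The immediate early median minus that of the cerebellar markers was −0.12 with a bootstrap SE of 0.129. An SE from 1 RNA pair holds no error between RNAs, so this difference cannot decide. A diet effect in SAMP8 brain, or a difference in what the mice did before the brains were taken, may also give this pattern, and with 1 RNA per group it was not tested.

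Genes called between the strains lay near each other on the chromosomes. Without the 15 measured genes of the interferon list and without counting neighbours of the same name stem, but with other interferon-induced genes such as Ifi27l2a and Tgtp1 kept in, 55 of 208 called genes had another called gene among 5 neighbours on either side, against a mean of 26.0 in random draws matched on expression (central 95%, 14 to 38.0), and 0 of 1000 draws gave as many. This is consistent with inherited blocks of chromosome that differ between the strains, stated as a hypothesis, and chromosome 17, which carries the major histocompatibility genes, had the highest share of called genes (24 of 721, 3.33%). Whether single probes fit the transcript of one strain badly remains open: 43.4% of other probes had the same sign and passed 1.5-fold (95% interval 33.5 to 53.8), a range that includes 50%, and probe sequences were not used here. The 99 other probes belong to 83 of the 394 called genes, and the interval treats them as independent. Each called probe was the brightest of its gene and had passed the rule, so 50% is not a neutral mark.

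Nasal mucosa transcripts, a list written after Cyp2g1 and Cyp2a5 were seen, had a diet median of −0.041 (percentile 2.13) with 2 of 13 lower and a strain median of 0.19 (percentile 100) with 3 of 13 higher, Cyp2a5, Cyp2g1 and Cyp2f2 (1.14 ± 0.03). The liver list had a strain median of 0.016 (percentile 78.2), with Apoa2 the member higher (2.14-fold), and the kidney list one of −0.14 (percentile 0).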
